A study of Mus musculus with 14 samples.

How the data were processed

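Gene expression was measured in microglia, the resident macrophages of the brain, which had been sorted from mouse cortex on the operated side. Total RNA was biotin-labelled and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, each of which held the RNA of 1 sample. The titles of the treated samples carry the abbreviation IPC, which is not explained in the sources used here, and the treatment label, ischaemia and reperfusion, was used. The markers used for the sort and the construction of the TLR4-/- allele are not given in the sources used here. The 14 samples fell into 4 groups by the genotype and surgery stated for each. These were wild type after ischaemia and reperfusion (I/R, arrays A to D, n = 4), wild type after sham surgery (arrays A to D, n = 4), TLR4-/- after I/R (arrays B, C and D, n = 3) and TLR4-/- after sham surgery (arrays A, B and D, n = 3). The labels do not say that each sample came from a separate animal, so the p-values measure the spread between these samples, which may be technical in part.

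The deposited values are on the log2 scale, with 1 value per array row and sample. Per the submitters' processing notes the authors used RMA in the oligo package, a method that corrects background, brings the arrays to a common distribution and summarises the probes of a row. No version of either was given. The array medians lay between 4.93 and 5.12, and no further normalization was applied in the main setting. RMA gives no detection call, so the signal of 1027 olfactory receptor genes, which microglia are not known to use, served as a stand-in for background. Their median was 2.93 and their 95th percentile 4.73, and 12261 of the 19938 genes (61.5%) had a mean above that percentile. A fold change against a group mean below it was measured against background signal. Array values have no sequencing depth, and the number of arrays limits the precision.

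Of the 35556 rows, 21789 carried 1 gene symbol, 1621 carried several and 12146 were unnamed here. Gene symbols came from the platform annotation, and 21698 of the rows with 1 symbol had a gene ID in a RefSeq gene table of assembly GRCm38.p6. That table was used for names and for which genes neighbour each other, and no coordinates are given. Rows with several symbols or none were left out of the gene tests. Of the genes, 999 had more than 1 row, and the row with the highest mean over all arrays stood for the gene, which left 19938 genes.

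All arrays entered a single linear model with 4 group means in limma 3.58.1 under R 4.3.3 (lmFit and eBayes). The series description names limma as the authors' package. Adjusted p-values are from Benjamini-Hochberg over all genes, and genes at an adjusted p under 0.05 were called. The 5 comparisons were I/R against sham in wild type, I/R against sham in TLR4-/-, the difference between these changes (wild-type change minus TLR4-/- change), TLR4-/- against wild type after sham, and TLR4-/- against wild type after I/R. In a simulation with 200 changed genes, run 5 times per comparison over 19938 genes, the share of genes changed 2-fold that was recovered was 96.4% for I/R in wild type. It was 92.8% for I/R in TLR4-/-, 67.5% for the difference of changes, 95.5% for the genotypes after sham and 94.9% for the genotypes after I/R. For genes changed 1.5-fold the share was 58.8%, 32.8%, 8.96%, 44.5% and 47.8% in the same order. The changed genes were divided among folds of 1.5, 2 and 4. Noise was drawn independently for each gene and array from the estimated spreads, without effects shared by an array or correlation between genes. The shares therefore apply to such noise and may not hold for the real arrays.

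The gene lists numbered 28. They covered type I interferon-stimulated genes, interferon-gamma-responsive GTPases and regulators, MHC class I and class II antigen presentation, DNA replication, mitosis, inflammatory cytokines and NF-kB targets, homeostatic microglia, disease-associated microglia, TLR4 signalling, other Toll-like receptors, type I interferons and their receptor pathway, immediate-early and heat-shock genes, hypoxia and glycolysis, NRF2 targets, cholesterol synthesis, the unfolded protein response, and complement and phagocytosis. The other lists held markers of monocytes, neutrophils, border-associated macrophages, T and NK cells, B cells, astrocytes, oligodendrocytes, neurons, endothelial cells with pericytes, and erythroid cells. A list's shift was tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 28 lists of a comparison. Camera with the correlation estimated from the data, and fry, which tests whether the members of a list move on balance in one direction, were run beside it. Of the 140 list shifts tested, 35 were called, and the mean, the median and the test had a common sign in each of these. They differed in sign in 16 shifts that were not called. The mean log2 value of a list per array was also compared by exact permutation tests, two-sided, adjusted by Benjamini-Hochberg over the 28 lists where stated.

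Groups, comparisons, gene lists, most tests and most alternatives were fixed before the data were examined. Exact permutation tests of list means were fixed only for the interferon-stimulated list, in the I/R comparisons and their difference. Those between genotypes or for other lists, and their adjustment over the 28 lists, were not in that plan. The rule for named genes took, for each comparison, the 10 called genes with the highest and the 10 with the lowest log2 fold change, or all called genes where fewer than 10 passed in a direction, or the 10 with the smallest p where none passed. Genes from rows with 1 symbol were eligible, without predicted models, olfactory and vomeronasal receptors, microRNAs or small nucleolar RNAs. For each list up to 4 members with the smallest p were named, and called members could be named with their list. Tlr4 was always named.

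The alternatives were a model of only the groups compared, eBayes with trend and robust settings, array weights, the replicate letter as a block, a filter that kept genes with at least 3 arrays above the median of all values, centring of each array on its median, quantile normalization, the mean of all rows of a gene, a test of all rows, an added fold threshold of 1.5, and leaving out each array in turn. For the lists they were the estimated correlation, fry, the median of the members and a shorter interferon list. A covariate for border-associated macrophage markers, and the genotype effect over both surgeries, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.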

Results

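The series profiled cortical microglia of male C57BL/6J mice aged 12 to 14 weeks, 72 h after a 15 min occlusion of the middle cerebral artery or after sham surgery. The treatment is given as in the treatment label, while the titles of the treated samples carry the abbreviation IPC, which is not explained in the sources used here. Both operations were carried out in wild-type mice and in mice without Toll-like receptor 4 (TLR4), a receptor for bacterial lipopolysaccharide and for molecules released from damaged tissue. The study asked whether ischaemia and reperfusion (I/R) switches on interferon-stimulated genes in microglia, and the TLR4-/- arm asked what the receptor contributes. There were 14 arrays, 4 for each wild-type group and 3 for each TLR4-/- group. Array medians lay between 4.93 and 5.12 on the log2 scale, and olfactory receptor genes, taken as background, had a 95th percentile of 4.73. Arrays of the same group correlated across all genes at r between 0.981 and 0.993. Wild-type sham array C correlated more closely with the TLR4-/- sham arrays (r between 0.987 and 0.992) than with its own group (r between 0.981 and 0.986). Likewise, TLR4-/- I/R array D correlated more closely with the wild-type I/R arrays (r between 0.9901 and 0.9915) than with its own group (0.9851 and 0.9898). The first principal component held 47.9% of the variance and separated the I/R arrays from the sham arrays, while the second held 8.98%.

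Tlr4 itself was measured by 1 array row, and its signal was present in both genotypes. The log2 values ran from 8.14 to 8.92 on the 8 wild-type arrays and from 7.62 to 8.47 on the 6 TLR4-/- arrays. The mean was lower in TLR4-/- by a difference of -0.37 on the log2 scale (exact permutation p = 0.0426, two-sided, 3003 splits). These splits ran over all arrays without regard to surgery. The difference was -0.46 among the sham arrays (exact permutation p = 0.0571) and -0.28 among the I/R arrays (exact permutation p = 0.257). In limma Tlr4 did not pass between the genotypes after sham (limma adjusted p = 0.920) or after I/R (limma adjusted p = 0.634). The part of the gene removed in the TLR4-/- mice and the positions of the probes are not given in the sources used here, so this row does not check the genotype labels. Leaving out single arrays moved the pooled exact p to between 0.0186 and 0.108. It rose above 0.05, so that the difference was no longer significant, without wild-type I/R array B or any wild-type sham array. The same held without TLR4-/- I/R array C or D, or TLR4-/- sham array B.

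In wild-type microglia, lists of cell division and interferon-stimulated genes rose after I/R. The gene with the highest change was from neither list. Fn1, which encodes the matrix protein fibronectin, rose from a log2 value of 4.95 ± 0.25 (SD, n = 4) to 10.48 ± 0.31 (SD, n = 4), a 46.4-fold change (log2 fold change 5.53, SE 0.17, limma adjusted p = 6.03e-12). Cxcl10, a chemokine induced by interferons, rose 19.4-fold, from 6.02 ± 0.29 to 10.30 ± 0.47 (limma adjusted p = 1.19e-09). Cd72, a surface receptor best known from B cells, rose 17.3-fold (log2 fold change 4.11, SE 0.18). A list of monocyte markers rose in the same arrays, by a mean of 1.15. Falls were smaller, and Gpr165, an orphan G protein-coupled receptor, fell by 1.62 on the log2 scale (SE 0.17, limma adjusted p = 3.9e-06).

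Across 19938 genes, limma called 1950 in wild type at an adjusted p under 0.05, of which 1226 were higher and 724 lower after I/R. At a fold of at least 2 the called genes numbered 498, with 471 higher and 27 lower. With each array centred on its median 1693 genes were called, 1300 of them higher, so the share of higher calls was 76.8% against 62.9% in the deposited scaling. The other named genes with the highest changes were Ch25h (4.78, SE 0.23), which makes the antiviral oxysterol 25-hydroxycholesterol, and genes of the dividing cell. These were the spindle checkpoint kinase Bub1 (4.77, SE 0.29), Birc5 (4.46, SE 0.32), the kinetochore gene Nuf2 (3.84, SE 0.19), Shcbp1 (3.81, SE 0.16), cyclin A2 gene Ccna2 (3.72, SE 0.28) and the topoisomerase gene Top2a (3.71, SE 0.21). Ch25h, Bub1, Nuf2 and Shcbp1 had sham means within the background range. The lowest changes were those of Klrd1, an NK cell receptor gene whose I/R mean lay in the background range (-1.63, SE 0.30), Gimap6 (-1.48, SE 0.21), Cd209a (-1.33, SE 0.31), Bank1 (-1.27, SE 0.18), Upk1b (-1.22, SE 0.16), the actin-bundling gene Fscn1 (-1.22, SE 0.13), Kcnrg (-1.20, SE 0.36), Tmem204 (-1.18, SE 0.14) and Sema4b (-1.14, SE 0.15). Tlr4 fell by 0.48 on the log2 scale (SE 0.15, limma adjusted p = 0.0485). The call of Tlr4 ended without I/R array A, C or D or sham array A, B or C (adjusted p between 0.0823 and 0.138), with centred arrays (0.106) and with trend and robust settings (0.0531). That of Kcnrg ended without any I/R array or sham array B, C or D (adjusted p between 0.0533 and 0.123), with centred arrays (0.0540) and with trend and robust settings (0.0651).

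The type I interferon-stimulated genes rose as a group in wild type. Of 46 measured members 40 rose and 0 fell over all genes, and 43 rose when adjusted over the list alone. The 4 members with the smallest p were the chemokine gene Cxcl10, Ifi27l2a (9.93-fold, log2 fold change 3.31, SE 0.22), the nucleic acid sensor Zbp1 (7.15-fold, 2.84, SE 0.24) and Ifit2, whose product binds viral RNA (7.33-fold, 2.87, SE 0.25). The mean change was 1.37 on the log2 scale (camera adjusted p = 1.03e-45, and adjusted p = 0.0136 with an estimated correlation). Array means of the list were 6.98 ± 0.09 (SD, n = 4) after sham and 8.34 ± 0.36 (SD, n = 4) after I/R, with no overlap (exact permutation p = 0.0286 over 70 splits, the smallest this design allows). That exact permutation p became 0.0800 after Benjamini-Hochberg adjustment over the 28 lists. With 0.0286 as the floor, the adjusted p could fall under 0.05 only if most lists reached that floor, so the adjustment cannot decide here. I/R array A had the lowest list mean of its group, 7.83, and leaving it out gave a mean change of 1.54. Of 12 interferon-gamma-responsive genes 3 rose, and 5 when adjusted over the list alone. These 3 were the checkpoint ligand gene Cd274 (1.17, SE 0.18) and the GTPase genes Iigp1 (1.44, SE 0.23) and Gbp4 (1.02, SE 0.27). Their list was called (mean 0.41, camera adjusted p = 0.0143), but not with an estimated correlation (adjusted p = 0.333 with an estimated correlation) nor without I/R array B (adjusted p = 0.0595) or without dim genes (0.0850).

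Genes of the cell cycle rose together in wild type. All 26 measured mitosis genes rose, over all genes and when adjusted over the list alone, with a mean change of 3.05 (camera adjusted p = 1.68e-68, and adjusted p = 0.00173 with an estimated correlation). The proliferation marker Mki67 changed by 3.42, the kinetochore motor gene Cenpe by 3.29, the kinase gene Ttk by 3.20 and the cyclin-dependent kinase gene Cdk1 by 2.63 on the log2 scale. The list mean went from 4.91 ± 0.25 (SD, n = 4) after sham to 7.96 ± 0.22 (SD, n = 4) after I/R. Of 25 DNA replication genes 20 rose, and 23 when adjusted over the list alone (mean 1.40, camera adjusted p = 3.73e-38, and adjusted p = 0.00108 with an estimated correlation). The ribonucleotide reductase gene Rrm2 rose 10.5-fold (log2 fold change 3.40, SE 0.20), the primase gene Prim1 8.06-fold (3.01, SE 0.18) and the helicase gene Mcm6 3.72-fold (1.89, SE 0.13).

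The disease-associated microglia list rose and the homeostatic list fell in wild type. Of 23 disease-associated genes 15 rose, and 17 when adjusted over the list alone (mean 1.20, camera adjusted p = 1.3e-18, and adjusted p = 0.00775 with an estimated correlation). They included lipoprotein lipase gene Lpl (7.88-fold, log2 fold change 2.98, SE 0.17), the glycoprotein gene Gpnmb (8.39-fold, 3.07, SE 0.20), the galectin gene Lgals1 (8.17-fold, 3.03, SE 0.21) and the fatty acid-binding protein gene Fabp5 (7.00-fold, 2.81, SE 0.21). Of 20 homeostatic genes 14 fell and 0 rose, and 18 fell when adjusted over the list alone. The mean change was -0.46 (camera adjusted p = 2.3e-11, but adjusted p = 0.0599 with an estimated correlation). Examples were the adhesion receptor gene Adgrg1 (1.99-fold lower), the purine receptor gene P2ry13 (log2 fold change -0.58, SE 0.10), the transcription factor gene Sall1 (-0.64, SE 0.13) and the microglial surface protein gene Tmem119 (-0.52, SE 0.10).

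**Figure D1:**
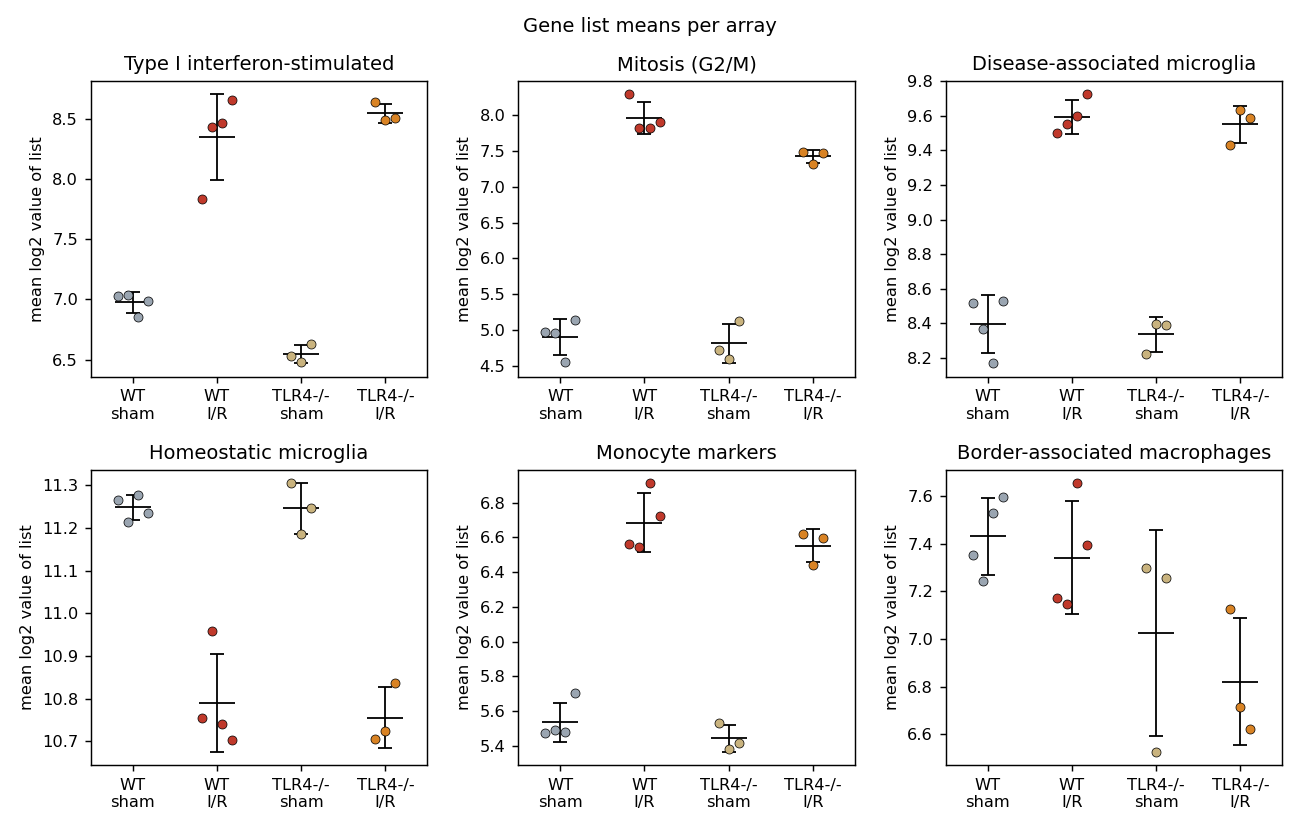
Mean log2 value per array over the genes of 6 lists (y axis, 1 panel per list) in the 4 groups; each dot is an array, the horizontal bar the group mean and the whiskers the SD. The interferon list averaged 6.98 in wild-type sham, 8.34 in wild-type I/R, 6.55 in TLR4-/- sham and 8.54 in TLR4-/- I/R arrays, and the mitosis list 4.91, 7.96, 4.82 and 7.42 in that order.

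Inflammatory genes were raised in part. Of 25 cytokine and NF-kB target genes 11 rose and 1 fell, and 12 rose and 1 fell when adjusted over the list alone (mean 0.68, camera adjusted p = 5.09e-08, but adjusted p = 0.112 with an estimated correlation). The chemokine gene Ccl5 rose 6.25-fold, Ccl2 2.88-fold, Ccl12 2.82-fold and the cytokine gene Tnf 2.59-fold. Il6 was the member that fell, by 1.06 on the log2 scale (SE 0.25). Of 19 hypoxia and glycolysis genes 7 rose, and 9 when adjusted over the list alone, among them the glycolytic genes Pgk1 (2.83-fold) and Ldha (2.05-fold) and the transcription factor gene Hif1a (1.59-fold). That list was called (mean 0.44, camera adjusted p = 1.66e-05), with adjusted p = 0.136 with an estimated correlation. In the complement and phagocytosis list 4 of 16 genes rose, as also when adjusted over the list alone. They were the scavenger receptor genes Msr1 (7.30-fold) and Cd36 (2.97-fold), the Fc receptor gene Fcgr4 (3.67-fold) and C4b (2.03-fold), and the list mean was 0.40 (camera adjusted p = 0.038, but adjusted p = 0.370 with an estimated correlation). In the cholesterol synthesis list Sqle and Cyp51 rose and Lss fell among 14 genes, with the same numbers when adjusted over the list alone (mean 0.19, camera adjusted p = 0.0446, but adjusted p = 0.346 with an estimated correlation). The complement call also ended without I/R array B or sham array B or C (adjusted p between 0.0553 and 0.0827), with array weights (0.0629) and without dim genes (0.145). The cholesterol call ended without I/R array B or D or sham array B or C (adjusted p between 0.0552 and 0.159), with array weights (0.0655), without dim genes (0.224), with centred arrays (0.0597) and with fry (0.0825).

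Markers of other cells were measured beside these genes. In the monocyte list 8 of 14 genes rose in wild type, and 10 when adjusted over the list alone (mean 1.15, camera adjusted p = 8.71e-14, and adjusted p = 0.00457 with an estimated correlation). Vim, which encodes the filament protein vimentin, rose 9.18-fold, the interferon-inducible Ms4a4c 6.33-fold, the adhesion receptor gene Cd44 3.01-fold and S100a4 2.40-fold. Ccr2, the chemokine receptor gene of classical monocytes, had a change of 0.41 that did not pass (limma adjusted p = 0.0763), while Chil3, a chitinase-like gene of monocytes and macrophages, rose by 1.19 within the background range (limma adjusted p = 0.0249). No shift was called for the lists of neutrophils (1 of 13 genes higher, mean 0.07), border-associated macrophages (0 of 10, mean -0.09), T and NK cells (0 of 13, mean -0.03), B cells (1 of 7 higher, Cd22, mean 0.11), astrocytes (3 of 11 lower, mean -0.33), oligodendrocytes (1 of 11 higher, mean -0.04), neurons (0 of 12, mean -0.21), endothelial cells with pericytes (2 of 10 higher and 1 lower, mean -0.03) or erythroid cells (Alas2 alone, -0.21).

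The remaining lists were not called in wild type. Toll-like receptor genes went both ways, as Tlr2, a receptor for bacterial lipoproteins, rose 2.01-fold (log2 fold change 1.01, SE 0.12) and Tlr9, a DNA sensor, fell by 0.52 on the log2 scale (SE 0.15), among 11 genes with a mean of 0.04. Of 16 TLR4 signalling genes 1 rose, the kinase gene Ikbke (0.53, SE 0.14), and the mean was -0.07. Of 15 genes for type I interferons and their receptor pathway 3 fell, Ifngr1, Irf5 and Sting1, and the mean was -0.11. Among 21 immediate-early and heat-shock genes 5 fell, Jun, Btg2, Jund, Rhob and Dusp1, while Nr4a1 rose (mean -0.13). In the NRF2 list 3 of 12 genes rose and 1 fell (mean 0.18), in the unfolded protein response list 2 of 14 rose (mean 0.10), in the MHC class I list 2 of 10 rose (mean 0.18) and in the MHC class II list 0 of 6 were called (mean 0.10).

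The TLR4-/- groups asked the same question without the receptor, and the same lists led the changes after I/R. Fn1 rose 42.3-fold, from 4.42 ± 0.07 (SD, n = 3), within the background range, to 9.82 ± 0.35 (SD, n = 3) (log2 fold change 5.40, SE 0.20, limma adjusted p = 8.84e-11). Cxcl10 rose 32.2-fold (log2 fold change 5.01, SE 0.24, limma adjusted p = 2.17e-09) and Cd72 22.4-fold (4.48, SE 0.21). Members of the interferon-stimulated list among the 10 highest were Cxcl10, Ifi27l2a (4.25, SE 0.25), Ifit2 (4.18, SE 0.29) and Ifit3 (4.09, SE 0.28). The others were Ch25h (4.42, SE 0.27), Ifi206 (4.31, SE 0.39), Birc5 (4.03, SE 0.37) and Ifit3b (3.88, SE 0.44). The sham means of Ch25h, Ifi206 and Ifit3b lay in the background range. The 10 lowest were Gpr165 (-1.84, SE 0.19), Angptl7 (-1.47, SE 0.26), Adam4 (-1.44, SE 0.39), Il6 (-1.34, SE 0.29), Cfap74 (-1.31, SE 0.20), Tmod1 (-1.31, SE 0.24), Cd209f (-1.31, SE 0.38), Stard9 (-1.27, SE 0.29), Gimap6 (-1.26, SE 0.24) and the co-stimulatory gene Cd80 (-1.25, SE 0.19). The change of Tlr4 did not pass (-0.30, SE 0.17, limma adjusted p = 0.355).

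Limma called 1628 genes after I/R in TLR4-/-, 1004 higher and 624 lower, and 504 of them at a fold of at least 2 (458 higher, 46 lower). With each array centred on its median 1385 genes were called, 987 of them higher, so the share of higher calls was 71.3%. The count dropped to 1071 without I/R array C and to 970 without sham array A. The call of Stard9 ended without I/R array C (adjusted p = 0.0678), that of Adam4 without I/R array B or C or sham array A or B (between 0.0755 and 0.140), and that of Cd209f without I/R array B or D or sham array A or D (between 0.115 and 0.210). The Cd209f call also ended with only the compared groups in the model (0.0698), trend and robust settings (0.0576), array weights (0.0639) and centred arrays (0.0602). The interferon-stimulated list had 42 of 46 genes higher and 0 lower, and 45 higher when adjusted over the list alone (a 3.99-fold mean change, camera adjusted p = 2.37e-61, and adjusted p = 0.00729 with an estimated correlation). Its array means were 6.55 ± 0.08 (SD, n = 3) after sham and 8.54 ± 0.08 (SD, n = 3) after I/R, and 3 against 3 arrays cannot give an exact permutation p below 0.1, the value reached. Interferon-gamma-responsive genes had 5 of 12 members higher, the same number when adjusted over the list alone (mean 0.71, camera adjusted p = 6.69e-05, but adjusted p = 0.113 with an estimated correlation).

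All 26 mitosis genes rose in TLR4-/- as well, also when adjusted over the list alone (mean 2.61, camera adjusted p = 4.01e-59, and adjusted p = 0.00319 with an estimated correlation). Mki67 rose 8.87-fold and Cdk1 5.96-fold. DNA replication genes rose in 22 of 25 cases, also when adjusted over the list alone (mean 1.33, camera adjusted p = 2.19e-33, and adjusted p = 0.00191 with an estimated correlation). The disease-associated list had 14 of 23 genes higher, and 17 when adjusted over the list alone (mean 1.22, camera adjusted p = 6.35e-19, and adjusted p = 0.00729 with an estimated correlation), with Lgals1 raised 9.59-fold and Lpl 5.41-fold. Homeostatic genes fell in 12 of 20 cases, and in 15 when adjusted over the list alone (mean -0.49, camera adjusted p = 3.5e-12, and adjusted p = 0.0483 with an estimated correlation). Monocyte markers rose in 6 of 14 cases, and in 7 when adjusted over the list alone (mean 1.11, camera adjusted p = 8.37e-10, and adjusted p = 0.0105 with an estimated correlation). Ccr2 had a change of -0.22 and did not pass.

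The other lists called in TLR4-/- lost the call with an estimated correlation. Inflammatory genes had 11 of 25 members higher and 1 lower, and 13 higher and 1 lower when adjusted over the list alone, led by Ccl12 (4.27-fold) and the interleukin gene Il1b (6.70-fold), with a mean of 0.86 (camera adjusted p = 1.18e-10, but adjusted p = 0.0525 with an estimated correlation). Hypoxia and glycolysis genes rose in 7 of 19 cases, also when adjusted over the list alone (mean 0.43, camera adjusted p = 0.000345, but adjusted p = 0.229 with an estimated correlation). Complement and phagocytosis genes rose in 4 of 16 cases, also when adjusted over the list alone (mean 0.48, camera adjusted p = 0.00412, but adjusted p = 0.278 with an estimated correlation, and adjusted p = 0.0960 without I/R array D). Immediate-early and heat-shock genes fell in 5 of 21 cases, and in 9 with 1 higher when adjusted over the list alone (mean -0.30, camera adjusted p = 0.000345, but adjusted p = 0.343 with an estimated correlation, and fry adjusted p = 0.0543). The members that fell were the transcription factor genes Jun and Klf6, and Btg2, Dusp1 and Rhob. The other 17 lists were not called in TLR4-/-, and the mean farthest from 0 among them was that of MHC class I genes (0.26, camera adjusted p = 0.0537).

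Setting the I/R changes of both genotypes against each other asks how much of the response depends on the receptor. Across 19938 genes the log2 fold changes correlated at Pearson r = 0.84 and Spearman rho = 0.59, where genes are not independent replicates and the comparisons share no arrays. Of the 1950 genes called in wild type, 1899 (97.4%) had the same sign in TLR4-/-, and the slope of the TLR4-/- change on the wild-type change was 0.90 among them. Genes called higher in both genotypes numbered 805 against 61.7 for independent lists, and genes called lower in both 337 against 22.7. With the genotypes fitted in separate models these were 711 against 55.5 and 234 against 14.5. Among genes called with opposite signs, 0 were higher in wild type and lower in TLR4-/-, and 1 was the reverse.

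**Figure D2:**
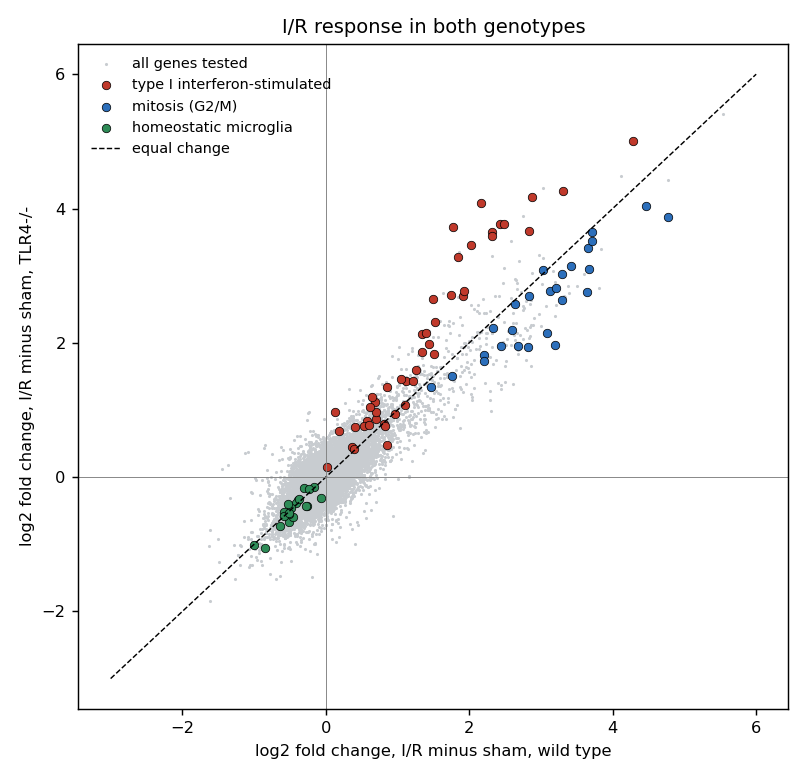
Log2 fold change of I/R against sham per gene in wild type (x axis) and in TLR4-/- (y axis); each dot is a gene and the dashed line marks equal change. Pearson r across the genes was 0.84, and 1899 of the 1950 genes called in wild type had the same sign in TLR4-/-.

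No single gene passed the test of the difference between the genotypes' I/R changes. Limma called 0 of 19938 genes, with 762 at an unadjusted p under 0.05 where 997 would arise by chance, and the smallest adjusted p was 0.382. The count was also 0 with trend and robust settings, array weights and quantile normalization. It was 1 without wild-type sham array C, where the interferon-induced membrane protein gene Ifitm3 passed (-1.70, adjusted p = 0.0142). Among genes called in wild type, the 95% interval of the difference reached a median of 0.47 on the log2 scale to either side, and for 1620 of 1950 it excluded a difference of 1. However, only 498 of the 1950 changed at least 2-fold in wild type. For the rest, a full loss of the change in TLR4-/- would also give a difference below 1, so this bound does not exclude dependence on the receptor. Of the 10 named genes with the smallest p, of which 0 passed, members of the interferon-stimulated list had negative values, Ifit3 (-1.92, SE 0.37), Rtp4 (-1.95, SE 0.39) and Ifitm3 (-1.44, SE 0.31). Positive values were those of the mitotic kinase gene Ttk (1.23, SE 0.21), the recombination gene Brca2 (0.98, SE 0.18), the cohesin acetyltransferase gene Esco2 (1.08, SE 0.23), Zfp599 (1.52, SE 0.27) and the kinesin gene Kif3a (0.85, SE 0.18). The sham means of Ttk, Brca2 and Esco2 lay in the background range in both genotypes, as did the wild-type sham and TLR4-/- I/R means of Zfp599, so these differences rest partly on background signal. The anaphase-promoting complex gene Cdc26 (-0.9995, SE 0.204) and Tada2a (-0.80, SE 0.16) had negative values. The difference for Tlr4 was -0.18 (SE 0.22).

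At the level of lists, interferon-stimulated genes had the larger mean change in TLR4-/- and mitosis genes the larger one in wild type. The mean I/R change of the interferon-stimulated list was 2.58-fold in wild type and 3.99-fold in TLR4-/-, a difference of -0.63 on the log2 scale (camera adjusted p = 1.65e-20, but adjusted p = 0.504 with an estimated correlation, and fry adjusted p = 0.448). It was negative for 41 of 46 members, of which 0 were called over all genes and 13 when adjusted over the list alone. An exact permutation of the genotype labels within each surgery gave p = 0.0114 over 1225 regroupings, which became 0.32 after Benjamini-Hochberg adjustment over the 28 lists. Leaving out wild-type I/R array A reduced the difference to -0.46. The mitosis list had a difference of 0.44, a larger change in wild type (camera adjusted p = 2.95e-10, but adjusted p = 0.504 with an estimated correlation), with 25 of 26 members positive, 0 called over all genes and 2 when adjusted over the list alone. Its exact permutation p was 0.163 over 1225 regroupings, and 0.907 after adjustment over the 28 lists. The mitosis means of the TLR4-/- sham arrays ran from 4.60 to 5.13, a range wider than this difference. Wild-type I/R array A had the highest mitosis mean of its group, 8.28, against 7.82 to 7.90 in the other arrays. The interferon-gamma list (-0.30, camera adjusted p = 0.0431, but adjusted p = 0.611 with an estimated correlation) and the inflammatory list (-0.18, camera adjusted p = 0.0434, but adjusted p = 0.861 with an estimated correlation) had 0 members called on either basis. The first of these calls ended without wild-type I/R array A or C, wild-type sham array B, TLR4-/- I/R array B or TLR4-/- sham array A or B (adjusted p between 0.0560 and 0.187). The other ended without wild-type I/R array A or B, wild-type sham array B or D, TLR4-/- I/R array C or D or TLR4-/- sham array A or B (adjusted p between 0.0501 and 0.754).

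After sham surgery the genotypes differed in a single called gene. Mid1, an X-linked gene for a microtubule-associated ubiquitin ligase, was lower in TLR4-/- at 6.09 ± 0.29 (SD, n = 3) than in wild type at 7.08 ± 0.08 (SD, n = 4), a log2 difference of -0.99 (SE 0.13, limma adjusted p = 0.0113). Limma called 1 of 19938 genes, with 1045 at an unadjusted p under 0.05, and 997 would arise by chance. The call of Mid1 ended without TLR4-/- sham array A (adjusted p = 0.118), without TLR4-/- sham array D (0.0543) or without wild-type sham array B (0.0711), and with only the compared groups in the model (0.196), and 10 genes were called without wild-type sham array C and 3 without wild-type sham array D.

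The interferon-stimulated list had a lower baseline in TLR4-/- sham microglia. The array means were 6.55 ± 0.08 (SD, n = 3) against 6.98 ± 0.09 (SD, n = 4), a difference of -0.43 with 40 of 46 members lower (camera adjusted p = 6.57e-19, but adjusted p = 0.535 with an estimated correlation). Over all genes 0 members were called, and 14 were lower when adjusted over the list alone. Rtp4 (-1.65, SE 0.28), Ifit3 (-1.42, SE 0.26) and Ifitm3 (-1.15, SE 0.22) had the smallest p among them, with limma adjusted p = 0.097, 0.150 and 0.183. The exact permutation p of the list mean was 0.0286 over 35 splits, the smallest this design allows, and 0.677 after adjustment over the 28 lists. With that floor, the adjusted p could fall under 0.05 only if most lists reached it. Markers of border-associated macrophages, the macrophages of meninges and vessels, moved with it. Their list was lower in TLR4-/- sham arrays by a difference of -0.41, with 10 of 10 members lower and 1 when adjusted over the list alone (camera adjusted p = 0.000157, but adjusted p = 0.535 with an estimated correlation), and the call ended without TLR4-/- sham array B (-0.15, adjusted p = 0.346). The same estimated-correlation value, adjusted p = 0.535 with an estimated correlation, applied to the other called lists, which had 0 members called on either basis. These were immediate-early and heat-shock genes (0.20, camera adjusted p = 0.00472), MHC class II genes (-0.36, camera adjusted p = 0.029) and DNA replication genes (-0.10, camera adjusted p = 0.029). The first ended without wild-type sham array A (adjusted p = 0.132) or TLR4-/- sham array D (0.0952), and the second without wild-type sham array D (0.322) or TLR4-/- sham array A (0.202) or D (0.0733). The last ended without wild-type sham array A (0.132) or D (0.228) or TLR4-/- sham array A (0.177) or B (0.232). The MHC class II and DNA replication calls also ended without dim genes (0.0827 and 0.287) and with centred arrays (0.0597 and 0.0598).

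After I/R the genotypes differed in 4 called genes. Phyhipl (0.96, SE 0.13, limma adjusted p = 0.0179) and Tnfsf4, which encodes the co-stimulatory OX40 ligand (0.78, SE 0.11, limma adjusted p = 0.0236), were higher in TLR4-/-, and for both the wild-type mean lay in the background range, as did the TLR4-/- mean of Tnfsf4. Mid1 (-0.91, SE 0.13, limma adjusted p = 0.0179) and Mns1, a gene of cilia and sperm flagella (-1.13, SE 0.18, limma adjusted p = 0.0416), were lower. The unadjusted p was under 0.05 for 1689 genes where chance gives 997. None of the 4 calls held without wild-type I/R array A or B or without any single TLR4-/- I/R array, where 0 genes were called, and 1 was called without wild-type I/R array C. With only the compared groups in the model the adjusted p of the 4 lay between 0.0652 and 0.132, and after quantile normalization Tnfsf4, Mns1 and Mid1 had 0.0657, 0.0619 and 0.0631. With the replicate letter as a block 0 genes were called, and the adjusted p of the 4 lay between 0.0856 and 0.175.

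**Figure D3:**
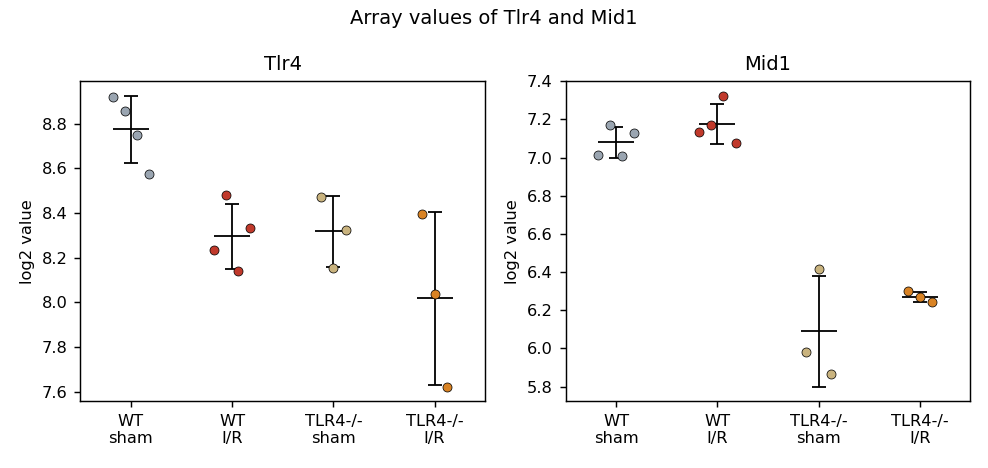
Log2 value of Tlr4 and of Mid1 on each array (y axis) in the 4 groups; each dot is an array, the horizontal bar the group mean and the whiskers the SD. Tlr4 overlapped between genotypes, with 8.14 to 8.92 in wild type and 7.62 to 8.47 in TLR4-/-, while Mid1 ran from 7.01 to 7.32 in wild type and from 5.87 to 6.42 in TLR4-/-.

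Mitosis genes were lower in TLR4-/- than in wild-type microglia after I/R. The list difference was -0.53 (camera adjusted p = 5.99e-20, but adjusted p = 0.248 with an estimated correlation), between array means of 7.42 ± 0.09 (SD, n = 3) and 7.96 ± 0.22 (SD, n = 4). All 26 members were lower, 0 of them called over all genes and 10 when adjusted over the list alone, with Ttk (-0.79, SE 0.15), Hmmr (-0.92, SE 0.22), Kif4 (-0.76, SE 0.20) and Cenpf (-0.68, SE 0.18) leading. The list's exact permutation p was 0.0286 over 35 splits, the smallest possible, and 0.32 after adjustment over the 28 lists, which that floor keeps high. Without wild-type I/R array A, which had the highest mitosis mean of its group (8.28), the list difference was -0.42. Border-associated macrophage markers were lower here too (-0.52, 10 of 10 members lower, 0 called over all genes and 1 when adjusted over the list alone, camera adjusted p = 7.05e-07, but adjusted p = 0.300 with an estimated correlation). DNA replication genes had a difference of -0.17 (camera adjusted p = 0.000562, but adjusted p = 0.470 with an estimated correlation). The interferon-stimulated list was 0.20 higher (camera adjusted p = 0.00917, but adjusted p = 0.730 with an estimated correlation, exact permutation p = 0.457), a difference that became 0.03 without wild-type I/R array A (adjusted p = 0.901) and whose call also ended without TLR4-/- I/R array B (0.105) or D (0.0694). Neither of these lists had a member called on either basis.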

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

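The model of the interferon list with a macrophage term, the leave-out of single sham arrays, the exchanges of pairs of arrays and the genotype effect over both surgeries were chosen only after the results had been seen.

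The difference between the genotypes in the I/R change of a list was singled out in 4 lists because camera tested the difference itself, at its preset correlation. The difference, wild-type change minus TLR4-/- change, was -0.63 for interferon-stimulated genes, -0.30 for interferon-gamma-responsive genes, 0.44 for mitosis genes and -0.18 for inflammatory genes, and 0 of the 4 passed with an estimated correlation or with fry.

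The interferon difference lay mainly in the sham arrays, where the list was lower in TLR4-/- by a difference of -0.43. A narrower spread of values on these arrays is argued against, since the difference was -0.41 after quantile normalization. A smaller share of border-associated macrophages, whose list differed by -0.41 over all sham arrays, is argued against as the whole cause, since the interferon difference was -0.41 (SE 0.09, 7 arrays) with the marker mean of each array in the model, although so few arrays leave a partial contribution open. The Tlr4 genotype and another difference between the mouse colonies cannot be told apart or tested here: with 1 sham array left out the difference was -0.40 or further from 0, but all TLR4-/- sham means lay so far below all wild-type ones that no leave-out could have closed it. With the estimated correlation the list was not called (adjusted p = 0.535 with an estimated correlation).

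The monocyte marker list rose after I/R in wild type, with 8 of 14 genes called, and the sort gate that could remove monocytes is not described. An interferon response of the members is argued against as the whole cause, since the median change of the 11 members not known as interferon-induced was 0.74. Infiltrating monocytes among the sorted cells could not be told from a change in the microglia, since Ccr2, Chil3 and F10, the members most specific to monocytes, had a median change of 0.41 and went from 0.09 for F10 to 1.19 for Chil3, the 1 of these that passed. In TLR4-/- the list rose by a mean of 1.11 while Ccr2 had -0.22, F10 -0.17 and Chil3 0.86, of which 0 passed, so there these members went both ways. From sham to I/R in wild type the log2 value went from 11.10 to 11.32 for Lyz2, from 9.12 to 10.39 for Tgfbi and from 5.90 to 9.10 for Vim, and values of different array probes do not rank the genes by abundance.

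Genes differing between the genotypes over both surgeries numbered 5 by limma, with 2050 genes at an unadjusted p under 0.05, and 2 without TLR4-/- sham array B and 3 without wild-type I/R array D, wild-type sham array A or TLR4-/- I/R array B or D. An exchange of 1 pair of arrays is argued against, since 0 of 24 such exchanges within surgery gave as many genes and the highest gave 2, as did the highest other of 100 drawn splits, of which 1, the real one, gave 5. An exchange of all genotype labels leaves the count at 5, so whether the genotypes as a whole were exchanged cannot be told from it. Passenger genes of the donor strain around Tlr4 may explain a part. Its neighbours were taken as the 100 tested genes on either side in chromosome order, whatever their distance. Of these 200 genes 35 (17.5%) had an unadjusted p under 0.05, against 2014 of 19737 other genes (10.2%; Fisher's exact test, one-sided, p = 0.00119). Alg6 was among these neighbours, and its distance from Tlr4 is not given here. Of 15908 overlapping runs of 200 neighbouring genes over the genome, 54 (0.339%) held at least as many. The other 4 called genes are not among the neighbours of Tlr4, and Mid1 and G530011O06Rik both lie on the X chromosome. Whether these X-linked genes differ for a shared reason was not tested. Whether the Tlr4 array row reads parts of the transcript outside the deletion was not tested here either.

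Arrays far from the others of their group turned up in 8 of 150 checks, where chance gives 7.50. The checks covered 28 lists and 47 genes in each wild-type group of 4 arrays, and the TLR4-/- groups were not checked. Some of these genes are list members, so the checks are not independent. The measure is the gap to the nearest array as a share of the group's range. Wild-type sham array D stood apart by 0.898 in the MHC class II list, where it was higher, by 0.926 in the monocyte list and by 0.945 in the neuron list. Wild-type sham array C stood apart by 0.907 for Ch25h and 0.868 for Bub1, both within the background range. Wild-type I/R array B was low in the immediate-early and heat-shock list (0.861), and wild-type I/R array A was high for Ttk (0.838) and low for Ifitm3 (0.873).

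Rows with no or several gene symbols were outside the gene tests and held a signal of their own. When they were tested, limma called 374 of 13767 in wild type after I/R (231 higher, 143 lower, 1831 at an unadjusted p under 0.05), and 213 of these were also called in TLR4-/- in the same direction.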

How the results depend on the processing

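The covariate for border-associated macrophage markers and the genotype effect over both surgeries were chosen after seeing the data. Of the counts, list numbers, levels and correlations, 200 values under an alternative kept their direction and their side of the threshold or stayed within the set bounds, 53 moved and 10 became weaker. Of the named genes' values 5675 were the same, 390 weaker, 1 stronger and 1 reversed, and of the list shifts 395 were the same, 87 weaker and 1 reversed. The cause was not tested except where the setting's own construction gives it.

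With only the compared groups in the model, which leaves fewer arrays to estimate the spread, the genotypes differed in 0 genes after sham and 0 after I/R. After sham they differed in 2 genes with trend and robust settings, 2 with array weights and 2 with all rows tested. After I/R they differed in 7 with array weights, 1 after quantile normalization, 1 with all rows tested and 0 with the macrophage covariate. With the replicate letter as a block, the block gave 2 genes after sham and 0 after I/R, and with this block the wild-type call of Kcnrg ended (adjusted p = 0.0558). Whether the letters pair the arrays is not stated. Of 18 pairs with a shared letter 3 correlated above 0.1 in their deviations from the group means, the median r was 0.0412 for a shared letter and -0.00517 for different letters, and 7 of 14 arrays had their best match across groups in an array of their own letter. An added fold threshold of 1.5 left 1183 genes in wild type, by its construction.

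The number of lists called after estimating the correlation was 5 for I/R in wild type, 6 in TLR4-/-, 0 for the difference of changes, 0 for the genotypes after sham and 0 after I/R. With fry it was 0 for the difference of changes, 0 after sham and 0 after I/R. Without dim genes, and again with arrays centred on their median, 3 lists were called after sham and 7 after I/R. The correlation of the I/R changes was 0.94 among genes called in wild type. The Tlr4 difference was -0.46 within sham arrays and -0.28 within I/R arrays, with fewer arrays in each.

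Leaving out 1 array at a time gave 1344 to 1962 genes for I/R in wild type and 970 (without TLR4-/- sham array A) to 1497 in TLR4-/-, with 1071 without TLR4-/- I/R array C. It gave 0 to 1 genes for the difference of changes, with 1 without wild-type sham array C. After sham it gave 0 to 10 genes, with 0 without wild-type sham array B or TLR4-/- sham array A or D, 10 without wild-type sham array C and 3 without wild-type sham array D. After I/R it gave 0 to 3, with 0 without wild-type I/R array A or B or any TLR4-/- I/R array, and 1 without wild-type I/R array C. Over both surgeries it gave 2 to 7, with 3 without wild-type I/R array D, wild-type sham array A or TLR4-/- I/R array B or D, and 2 without TLR4-/- sham array B. The number of lists ran from 2 to 7 for the difference of changes, with 2 without wild-type I/R array A or wild-type sham array B and 7 without TLR4-/- I/R array C. It ran from 3 to 7 after sham, with 3 without wild-type sham array A or D or TLR4-/- sham array A or B and 7 without wild-type sham array C. It ran from 4 to 8 after I/R, with 8 without wild-type I/R array B and 7 without TLR4-/- I/R array C. The Tlr4 difference ran from -0.43 to -0.26, and the correlation from 0.797 to 0.842.

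A reversed sign came from leaving out 1 array in 2 cases. The interferon-stimulated list after I/R differed by 0.0281 without wild-type I/R array A, where the test against other genes pointed below 0, and by up to 0.302 without wild-type I/R array D. For Tlr4, genes whose I/R change differs between genotypes being the comparison, the value ran from -0.378 without TLR4-/- I/R array D to 0.00914 without TLR4-/- I/R array B. The mean interferon change kept its direction in every leave-out, with 1.26 to 1.54 in wild type, and -0.73 to -0.46 for the difference of changes. RMA signal near background limits the folds of genes whose lower group lies there, and the dim filter kept 11832 genes.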

Other observations

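The splits of the samples, and the genotype effect over both surgeries, were chosen only after the results had been seen.

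Mid1, which encodes a microtubule-associated ubiquitin ligase, was lower in TLR4-/- arrays over both surgeries (log2 difference -0.95, SE 0.09, limma adjusted p = 0.000176) and lay below every wild-type array on each of the 6 TLR4-/- arrays. The nucleotidase gene Entpd4 (-0.83, SE 0.11) and Alg6, whose product adds glucose in N-glycan assembly (-0.75, SE 0.11), were lower too. Phyhipl was higher (0.58, SE 0.09), but its mean lay in the background range in every group except TLR4-/- I/R (5.26). The remaining call was G530011O06Rik (-1.01, SE 0.13), a gene outside the naming rule that was chosen after its values were seen.

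Counts of called genes were compared with those of other splits of the same arrays into groups of the same sizes. For I/R in wild type 1 of 35 splits, the real one with 1950 genes, gave as many, a share under 0.05 and the smallest that 35 splits allow. The highest other gave 1, but the other splits mix I/R and sham arrays within a group, which widens the spread there. For I/R in TLR4-/- there were 10 splits, too few for a share under 0.05, with 1628 genes in the real split and 0 in the highest other. For the genotypes after sham chance cannot be excluded, since 7 of 35 splits gave at least the 1 gene of the real split. The highest other gave 20, several times the real count, which points to a structure of the samples that was not tested further. Leaving out wild-type sham array C raised the count, and that array correlated more closely with the TLR4-/- sham arrays than with its own group. Such a correlation was not particular to it, as TLR4-/- I/R array D was likewise closer to the wild-type I/R arrays. For the genotypes after I/R 1 of 35 splits, the real one, gave as many as 4 genes, a share under 0.05, but the highest other gave 3. The margin was thus 1 gene, and the count was 0 without wild-type I/R array A or B or any TLR4-/- I/R array and with only the compared groups in the model. For the difference of changes the real count was 0 (limma, 762 genes at an unadjusted p under 0.05), so all 100 splits drawn of 1225 gave as many, and the highest other gave 1.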
